A study of Medicago truncatula with 6 samples.

How the data were processed

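Root RNA of Medicago truncatula was sequenced from plants of the R108 background and from the spx1spx3 mutant, both grown on low phosphate, with 3 libraries per genotype. Total RNA was extracted with TRIzol and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The same protocols speak of technical replicates for each sample, and nothing in the labels says that the libraries of a genotype came from separate plants or cultures. All p-values therefore measure only the spread between these libraries, which may be technical. Groups and replicate numbers were taken from the sample titles.

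The authors deposited a table of 50607 genes that holds an RPKM value and a TPM value for each library, rounded to 2 decimals, per the file headers. The TPM values deposited for each library sum to 1000000 over the table, so a gene's TPM is its share of the transcripts in that library and depends on all other genes. Within a library, the RPKM values deposited by the authors are a fixed multiple of the TPM values. The authors also deposited a table of 1020 selected genes with the ratio of mean TPM, empty for 140 of them, and with a log2 fold change in spx1spx3 against wild type, per the file headers. How the deposited log2 fold change was made is not given in the sources used here. It differed from the log2 ratio of mean TPM by a median of 0.134 and by up to 2.19, as for MtrunA17Chr2g0301181, deposited at -2.10 with a log2 ratio of -4.29. A further deposited table lists 10 genes with their TPM and the log2 ratio of mean TPM. The aligner, the counting program, the genome build and the annotation version are not given in the sources used here. Gene identifiers are of the MtrunA17 series, which belongs to the A17 reference strain, while the plants are of the R108 background. Sequence that differs between the strains can therefore lower the value of a gene in both genotypes.

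Gene descriptions were taken from the table of 1020 genes, which gives an informative description for 874 genes and an older locus name for 808. The RefSeq gene table supplied for this work (assembly MtrunA17r5.0-ANR) was not used, since 0 of the tested gene identifiers were found in it. Gene coordinates, gene lengths, GC content and annotated terms were not analysed here, and no enrichment of annotated terms was run. For this reason, the gene lists could be matched only among genes that the authors had selected on these samples, and the direction of a list is not independent evidence.

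The planned test was one for read counts. Because the deposited units were TPM and RPKM, the test planned for normalized values was used in its place. Genes with a mean TPM of at least 1 in either genotype were kept, which left 27397 genes, and limma 3.58.1 in R 4.3.3 was fitted to log2(TPM + 1) with a mean-variance trend and robust estimation. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, with no fold threshold. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, among the described genes of the authors' table and for lists with at least 3 members. The background of the list test was chosen after seeing the data, as only these genes have descriptions. fry tested whether the members of a list move on balance one way or change in either direction. Fisher's exact test compared the direction of a list's members with that of the other described genes. Figures were drawn with matplotlib 3.10.9.

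The lists, matched on words in the descriptions, covered flavonoid and isoflavonoid biosynthesis, the general phenylpropanoid pathway, the phosphate starvation response, strigolactones, nodulation, arbuscular mycorrhiza, nitrogen uptake and assimilation, iron acquisition and storage, defence proteins, MATE and ABC-G transporters and peroxidases. Photosynthesis, dividing cells, heat shock proteins and the cytosolic ribosome were included as markers of other tissue or handling. The lists, the test and the rule for named genes were fixed before the data were examined. The rule took SPX1 and SPX3. It took the 6 higher and 6 lower genes with the largest change among called genes with non-overlapping libraries, a mean of at least 5 TPM in the higher group and a description of a protein. Only genes of the authors' table have descriptions, and each of these has a mean of at least 5 TPM in both groups. The named genes are therefore the largest changes among those genes, not among all called genes. For each main list it took up to 3 members with the smallest adjusted p, or 5 for the flavonoid and phosphate lists, and for the other lists the member with the highest mean.

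The depth of the libraries cannot be read from TPM. Peaks in the ratios of low TPM values between libraries, where genes hold few reads, gave an estimate of relative depth. With wild type replicate 2 set to 1, wild type replicates 1 and 3 were at 0.907 and 0.989, and spx1spx3 replicates 1, 2 and 3 at 0.881, 0.8995 and 0.842. No counting interval can be given without read totals. The test was checked on simulated data with the spread of these 27397 genes. Of 100 genes changed by a fold of 2, 43% were recovered, and of 100 changed by a fold of 4, 82%. No recovered gene had the wrong direction, and 6 unchanged genes were called, 4.58% of all calls. The simulation changed only 200 genes, drawn from the more abundant ones, with independent noise, while 4661 genes were called in the data. Its adjusted p threshold was therefore stricter, and these shares need not hold for the data.

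The alternatives were no filter on low values, a pseudocount of 0.1, a log2 fold threshold of 1, the replicate number as a block, each library left out in turn and an estimated inter-gene correlation for the lists. Scaling by the median of ratios, RPKM in place of TPM and a floor of 5 TPM in both groups were added after seeing the data. In the median-of-ratios scaling, each library's TPM values were divided by the median ratio to the geometric mean over genes above 0 in all libraries.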

Results

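The data set holds 6 root transcriptomes of Medicago truncatula, a model legume, grown on low phosphate. Of these, 3 were from wild type plants of the R108 line and 3 from spx1spx3, a double mutant of SPX1 and SPX3. SPX proteins bind inositol pyrophosphates, which report the phosphate state of the cell, and restrain the transcription factors of the phosphate starvation response. Between 32265 and 32979 genes had a TPM above 0 in a library, and between 25815 and 26346 had a TPM above 1. The 100 most abundant genes took between 19.2% and 22.04% of the TPM of a library. The ratio of TPM to RPKM, fixed within a library, was 2.77 to 2.88 in wild type and 2.97 to 3.02 in spx1spx3. Correlations of log2(TPM + 1) across genes, which are not independent replicates, were 0.954 to 0.970 within wild type and 0.948 to 0.968 within spx1spx3. Between the genotypes they were 0.880 to 0.932. The first principal component, with 55.7% of the variance, separated the genotypes. The estimated depth of the spx1spx3 libraries was 0.842 to 0.8995 of that of wild type replicate 2, below the 0.907 to 1 of the wild type libraries.

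The mutated genes were examined first. MtrunA17Chr3g0137851 is described in the authors' deposited table as SPX domain-containing 2-like, a name that does not by itself point to SPX1. It is paired there with the locus Medtr3g107393, which is taken here as SPX1 from the published naming of that locus. The gene stood at 18.90, 7.08 and 28.85 TPM in the wild type libraries and at 4.18, 8.61 and 9.88 TPM in the spx1spx3 libraries. The log2 fold change was -1.05 with a standard error of 0.51 and a 95% interval of -2.25 to 0.15. With an adjusted p of 0.183 (limma) the gene did not pass the test, which does not show that it was unchanged. Without wild type replicate 2, the lowest wild type library, the log2 fold change was -1.58 with an adjusted p of 0.0385. Without wild type replicate 3, the highest, it was -0.64 with an adjusted p of 0.414. An insertion mutant can still make reads outside the inserted position, and the identity of the gene does not come from the tables, so its level is a weak check of the genotype. SPX3 was not analysed here.

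The comparison of the genotypes addressed which root genes depend on SPX1 and SPX3 on low phosphate, with flavonoid biosynthesis as the study's focus. Of 14 flavonoid and isoflavonoid genes in the authors' table, 6 fell in spx1spx3, among them a 2-hydroxyisoflavanone dehydratase from 99.0 ± 16.3 to 26.4 ± 5.36 TPM (SD, n = 3). All 3 ferritin genes of the authors' table, which encode iron storage proteins, also fell. Both genes described as high-affinity nitrate transporters rose, one of them from 160.6 ± 53.2 to 572.5 ± 169.6 TPM. Of 13 peroxidases selected by the authors, 8 rose, 2 fell and 3 did not pass the test. With 1 library left out, 2 to 8 of these peroxidases rose, the fewest without spx1spx3 replicate 2 or 3. With all 6 libraries, genes for 3 germins and for a high-affinity phosphate transporter rose. The 6 named genes with the largest falls were 2 described as ERF017, 2 for U-box proteins, a nuclease HARBI1 and a CCCH zinc finger gene. Of the 35 named genes that passed the test, 12 passed without any 1 library, among them the dehydratase, 1 ferritin, the 3 germins and both U-box genes. The other 23 did not pass without spx1spx3 replicate 2, with adjusted p of 0.0519 and 0.052 for the nitrate transporters, 0.0606 and 0.082 for 2 ferritins and 0.0785 for the phosphate transporter. For the genes described as ERF017, HARBI1 and the CCCH zinc finger it was 0.0605 to 0.061.

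The flavonoid and isoflavonoid list had 14 members in the authors' table, all lower in spx1spx3, with log2 fold changes from -1.87 to -0.77 and a median of -0.99. At the adjusted p over all genes, 6 fell, and 8 did when adjusted over the list alone. The authors chose these genes on these samples, so neither count is independent evidence of the direction. The dehydratase MtrunA17Chr1g0205871, named for the enzyme that dehydrates the product of isoflavone synthase, had a log2 fold change of -1.87 with a standard error of 0.19 and an adjusted p of 0.00628. Chalcone synthase catalyses the first step of flavonoid synthesis. Among genes described as members of the chalcone and stilbene synthase family, MtrunA17Chr1g0201381 fell from 38.1 ± 16.3 to 13.5 ± 3.29 TPM and MtrunA17Chr1g0201391 from 68.4 ± 31.9 to 24.2 ± 7.47 TPM. MtrunA17Chr1g0201421 and MtrunA17Chr1g0201371 both fell by 1.45 on the log2 scale, with adjusted p of 0.0374 and 0.0267. These similar genes can share reads, so their values are not separate observations. The sixth gene that fell, named after its values were seen, was the UDP-glucose flavonoid 3-O-glucosyltransferase MtrunA17Chr5g0442521, with a log2 fold change of -0.85. It passed with all 6 libraries and without wild type replicate 1, but without any other library the adjusted p was 0.066 to 0.126. Only 5 of the 14 members were not chalcone synthases, so further chalcone synthase genes were among the 8 members that did not pass with all 6 libraries. The 4 chalcone synthase family genes that fell did not pass without wild type replicate 3 (adjusted p from 0.0548 to 0.0748) or spx1spx3 replicate 2 (0.0937 to 0.117). They also did not pass without spx1spx3 replicate 3 (0.0871 to 0.107), nor did 3 of them without wild type replicate 1 (0.0501 to 0.0689). With no filter on low values 3 of the 14 members fell, as MtrunA17Chr1g0201391, MtrunA17Chr1g0201421 and the glucosyltransferase had adjusted p of 0.0582, 0.0591 and 0.0654. The 3 genes described as isoflavone synthases did not pass the test, and the most abundant of them, MtrunA17Chr4g0046331, stood at 669.2 ± 303.2 TPM in wild type and 349.98 ± 62.98 TPM in spx1spx3 (adjusted p = 0.182). Its log2 fold change went from -0.82 to -1.28 without wild type replicate 2, with an adjusted p of 0.0191.

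As a set, the flavonoid list did not stand apart from the other described genes of the authors' table, 79.9% of which were lower. Camera gave an adjusted p of 0.489 with the preset correlation and 0.904 with an estimated correlation. Fisher's exact test of direction gave an adjusted p of 0.170. fry, which asks only whether the members move on balance one way, gave an adjusted p of 0.014. The authors had selected all 14 members as changed on these libraries, and all were lower, so that balance was built in by the selection. Leaving out a library moved the count of members that fell from 6 to 3 without wild type replicate 1 and to 11 without wild type replicate 2. It was 1 without wild type replicate 3, spx1spx3 replicate 2 or spx1spx3 replicate 3. Wild type replicate 2 was the lowest wild type library for 10 of the 14 members, against 305 of the 815 lower genes of the authors' table. The isoflavone synthase MtrunA17Chr4g0046331 stood at 320.9 TPM there, against 812.5 and 874.2 TPM in wild type replicates 1 and 3. The shoot marker MtrunA17Chr4g0051941, a chlorophyll-binding protein gene, had the same order, with 343.9, 92.7 and 356.6 TPM in wild type replicates 1, 2 and 3. The dehydratase had another order, with 111.7, 104.6 and 80.6 TPM, and the chalcone synthase family genes that fell were also highest in wild type replicate 1. The authors' deposited table of 10 genes holds chalcone synthases, the dehydratase and glycosyltransferases. Of these genes 9 fell, or 6 with no filter on low values, and the median log2 fold change in the fit here was -1.43. The authors chose them on the same libraries. They include the dehydratase and the 4 chalcone synthase family genes that fell above, so they are no independent support. The count that fell was 5 without wild type replicate 1, 4 without wild type replicate 3 and 3 without spx1spx3 replicate 2 or 3. The general phenylpropanoid list had 1 member, a phenylalanine ammonia-lyase (MtrunA17Chr5g0448361), the entry enzyme of the pathway, which fell from 28.9 ± 5.11 to 14.5 ± 2.99 TPM (adjusted p = 0.0231). It did not pass without wild type replicate 1 (adjusted p = 0.0643) or 3 (0.0685) or without spx1spx3 replicate 2 (0.0843) or 3 (0.0811).

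**Figure D1:**
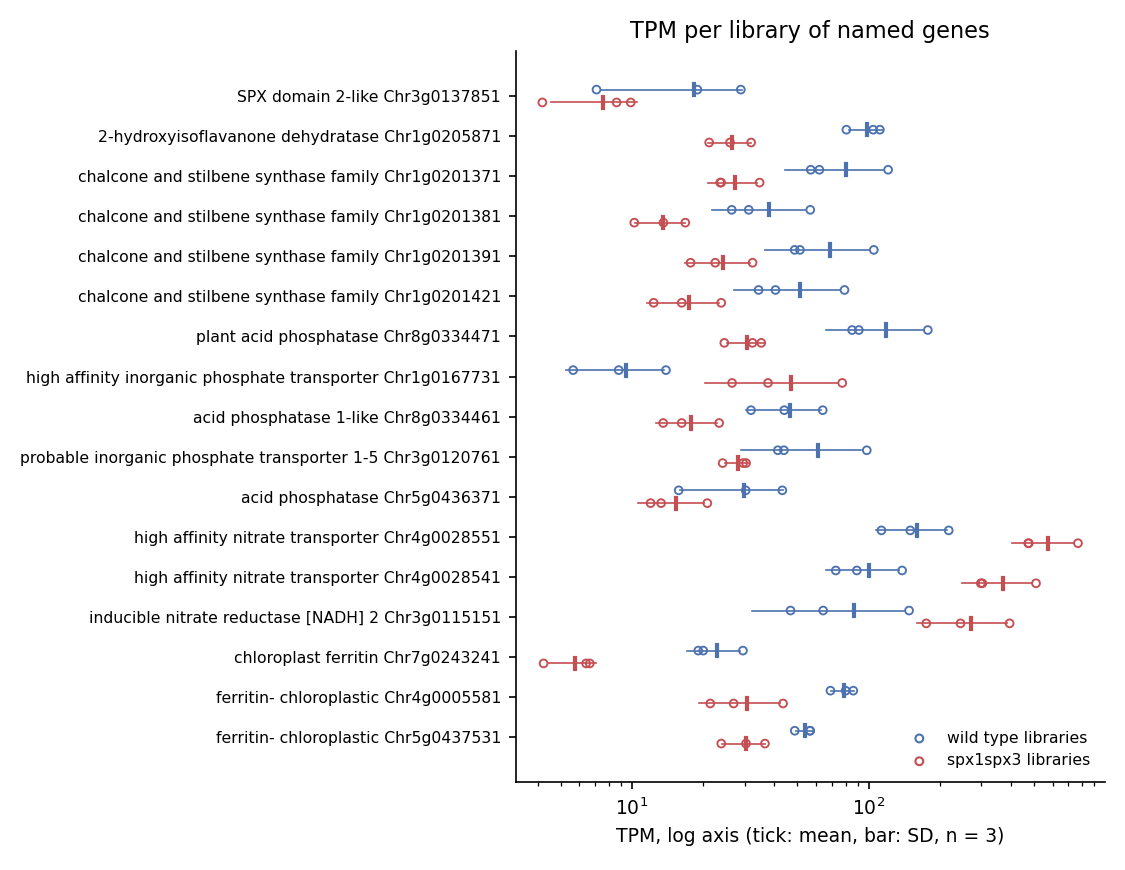
TPM on a log axis of SPX1 and of named genes of the flavonoid, phosphate, nitrogen and iron lists, with open circles for the 3 libraries of each genotype, ticks for means and bars for the SD. The wild type and spx1spx3 libraries did not overlap for the dehydratase, at means of 99.0 and 26.4 TPM, and overlapped for SPX1, at means of 18.3 and 7.56 TPM.

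The phosphate starvation list had 6 members in the authors' table, of which 5 were lower and 1 was higher. At the adjusted p over all genes 2 fell and 1 rose, and adjusted over the list alone 3 fell and 1 rose, again for genes that the authors chose on these samples. The acid phosphatase MtrunA17Chr8g0334471 fell from 118.1 ± 52.0 to 30.7 ± 5.50 TPM, and the acid phosphatase MtrunA17Chr8g0334461 from 46.6 ± 16.2 to 17.7 ± 5.07 TPM. Acid phosphatases release phosphate from organic compounds. The high-affinity phosphate transporter MtrunA17Chr1g0167731 rose from 9.45 ± 4.18 to 47.2 ± 26.8 TPM, with a log2 fold change of 2.14, a standard error of 0.44 and an adjusted p of 0.0241. Another phosphate transporter, MtrunA17Chr3g0120761, had a log2 fold change of -0.99 (adjusted p = 0.0803) and the acid phosphatase MtrunA17Chr5g0436371 one of -0.84 (adjusted p = 0.154). The sixth member was SPX1, one of the mutated genes, so the counts, the median and the list tests include the mutation itself. The median of the list was -1.02, while camera pointed upward relative to the other table genes (adjusted p = 0.901). fry gave an adjusted p of 0.0119 for a balance in one direction, which is no independent support for genes selected as changed on these libraries. Without spx1spx3 replicate 2, none of the 6 passed the test, without spx1spx3 replicate 3 none fell, and without wild type replicate 1 only 1 fell and none rose. The adjusted p of MtrunA17Chr8g0334471 was 0.0595 and 0.0523 without spx1spx3 replicate 2 and 3, and that of the transporter MtrunA17Chr1g0167731 was 0.0785 without spx1spx3 replicate 2 and 0.0698 without wild type replicate 1. MtrunA17Chr8g0334461 did not pass without wild type replicate 1 (0.0667) or 2 (0.0507) or spx1spx3 replicate 2 (0.0966) or 3 (0.0916). Without wild type replicate 2, 4 fell, among them SPX1 itself at -1.58 (limma, adjusted p = 0.0385). In that fit MtrunA17Chr3g0120761 was at -0.59 (adjusted p = 0.0441) and MtrunA17Chr5g0436371 at -1.22 (adjusted p = 0.0364). Without wild type replicate 3, MtrunA17Chr5g0436371 was at -0.52 (adjusted p = 0.351).

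Nitrogen uptake and assimilation had 3 members in the authors' table, and all 3 rose, with a median log2 fold change of 1.84. The nitrate transporters MtrunA17Chr4g0028551 and MtrunA17Chr4g0028541 had log2 fold changes of 1.84 and 1.88, with standard errors of 0.30 and 0.31 and adjusted p of 0.0142 and 0.0143. Nitrate reductase (MtrunA17Chr3g0115151), which reduces nitrate to nitrite, went from 86.5 ± 54.3 to 271.7 ± 112.2 TPM with an adjusted p of 0.0483. It did not pass under median-of-ratios scaling (0.0836), with RPKM (0.0621), with no filter (0.0749) or with a pseudocount of 0.1 (0.0505). Camera gave the list an adjusted p of 0.00229, which was lost with an estimated correlation (adjusted p = 0.352), and Fisher's exact test of direction gave 0.0229. Both transporters share a description and may share reads. All 3 members, nitrate reductase included, had the same order of TPM over all libraries, so that order does not single out shared reads. The members may therefore not be the separate ones that Fisher's test counts. No member passed without spx1spx3 replicate 2, where both transporters had an adjusted p of 0.052. Nitrate reductase also missed the threshold without wild type replicate 1 (0.13) or 3 (0.122) and without spx1spx3 replicate 1 (0.107) or 3 (0.0794). The iron list had 3 members, all ferritins, and all 3 fell. Their log2 fold changes were -1.81 for MtrunA17Chr7g0243241, -1.38 for MtrunA17Chr4g0005581 and -0.83 for MtrunA17Chr5g0437531, with standard errors of 0.22, 0.25 and 0.17. Camera gave an adjusted p of 0.489 for the iron list. Of the 3 ferritins, 1 passed without wild type replicate 3, spx1spx3 replicate 1 or spx1spx3 replicate 2, and 2 without wild type replicate 1. MtrunA17Chr7g0243241 passed throughout, while the fits in which the others missed the threshold gave an adjusted p of 0.0507 to 0.0606 for MtrunA17Chr4g0005581 and 0.0514 to 0.082 for MtrunA17Chr5g0437531.

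Of 13 peroxidases in the authors' table, 8 rose, 2 fell and 3 did not pass the test, with 9 higher and 3 lower when adjusted over the list alone. These enzymes of the cell wall and apoplast use hydrogen peroxide to oxidise phenolic compounds, among them lignin precursors. The peroxidase P7-like gene MtrunA17Chr4g0013181 rose from 7.08 ± 1.15 to 34.5 ± 7.97 TPM (adjusted p = 0.00618), and the cationic peroxidase MtrunA17Chr2g0279041 from 112.2 ± 38.9 to 319.8 ± 59.9 TPM (adjusted p = 0.0159). MtrunA17Chr5g0405991 rose by 1.37 on the log2 scale. The 2 that fell, named after their values were seen, were MtrunA17Chr2g0299691 at -0.97 and MtrunA17Chr5g0402571 at -1.42. The list stood apart from the other described genes by camera (adjusted p = 8.9e-05) and by Fisher's exact test (adjusted p = 0.0008), but not with an estimated correlation (adjusted p = 0.114). The count that rose was 3 without wild type replicate 3 and 2 without spx1spx3 replicate 2 or 3, and in these fits none fell and the cationic peroxidase had an adjusted p of 0.052 to 0.0614. MtrunA17Chr2g0299691 also missed the threshold without spx1spx3 replicate 1 (0.0515), and MtrunA17Chr5g0402571 without wild type replicate 1 (0.107) or 2 (0.0906) and with no filter on low values (0.0719).

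Of 7 defence proteins, 5 fell, 1 rose and 1 did not pass the test, over all genes and over the list alone. A pathogenesis-related STH-2-like gene (MtrunA17Chr4g0067841) fell from 108.7 ± 13.9 to 49.1 ± 4.15 TPM. A disease resistance response gene (MtrunA17Chr7g0259101) and a class-10 pathogenesis-related gene (MtrunA17Chr2g0295081) fell by 1.53 and 1.00. The gene that rose, named after its value was seen, was a pathogenesis-related PR-1-like gene (MtrunA17Chr4g0072781) at 1.47, which did not pass under median-of-ratios scaling (adjusted p = 0.0935), with RPKM (0.0556) or with no filter on low values (0.0596). With no filter 2 of the 7 fell, and the class-10 gene had an adjusted p of 0.0540. Camera gave the list an adjusted p of 0.901, and between 1 and 4 members fell when any one library was left out. The disease resistance response gene passed without wild type replicate 2 or 3 (adjusted p from 0.0522 to 0.0871 without any other library), the class-10 gene without wild type replicate 2 only (0.0563 to 0.112) and the PR-1-like gene without wild type replicate 1 only (0.0743 to 0.116). Of the transporters of the MATE and ABC-G families, which export secondary metabolites, the pleiotropic drug resistance 1-like gene MtrunA17Chr1g0148811 went from 29.3 ± 5.44 to 83.9 ± 31.3 TPM (adjusted p = 0.0281, and 0.0564 under median-of-ratios scaling). Of the fits with 1 library left out, it passed only without spx1spx3 replicate 1, with an adjusted p of 0.053 to 0.0921 in the others. An ABCG5-like gene (MtrunA17Chr3g0130331) had a log2 fold change of -1.21 and an adjusted p of 0.0988.

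The strigolactone and nodulation lists had 1 member each in the authors' table, and neither passed the test with all 6 libraries. A probable strigolactone esterase (MtrunA17Chr1g0152551) stood at 95.5 ± 64.5 TPM in wild type and 25.5 ± 4.25 TPM in spx1spx3 (log2 fold change -1.54, adjusted p = 0.121). Without wild type replicate 2 its log2 fold change was -2.30 with an adjusted p of 0.0115. A gene described as nodulation-signaling pathway 2-like (MtrunA17Chr7g0243151) had a log2 fold change of -0.95 with a standard error of 0.32 (adjusted p = 0.0879). The mycorrhiza, dividing-cell and ribosome lists had 0 members in that table and were not tested. Of the lists for other tissue or handling, photosynthesis had 2 members that did not pass, the more abundant (MtrunA17Chr4g0051941) at 264.4 ± 148.8 TPM in wild type and 130.1 ± 0.597 TPM in spx1spx3 (adjusted p = 0.295). Without wild type replicate 2, the lowest wild type library for both members, the log2 fold change of MtrunA17Chr4g0051941 went from -0.79 to -1.42 with an adjusted p of 0.0116. Without wild type replicate 1 or 3 it was -0.48 or -0.45. The only heat shock member, a heat shock cognate 70 kDa gene (MtrunA17Chr4g0031321), rose from 33.4 ± 4.92 to 82.6 ± 10.6 TPM (adjusted p = 0.00893).

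**Figure D2:**
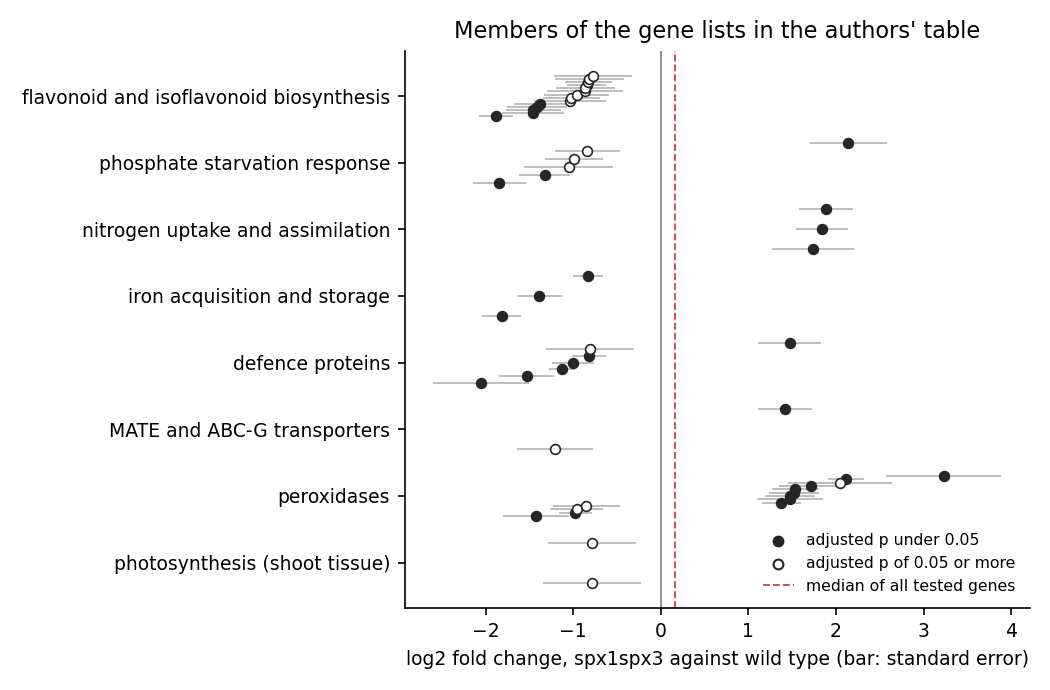
Log2 fold change with its standard error of each list member in the authors' table, for lists with 2 or more members, filled where the adjusted p was under 0.05. All 14 flavonoid members lie left of 0, between -1.87 and -0.77, all 3 nitrogen members lie right of 1.7, and the dashed line marks the median of all tested genes at 0.17.

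Among the described genes of the authors' table, the 6 largest increases named by the rule included 3 genes described as germin subfamily 1 member 7, a family of apoplastic glycoproteins. MtrunA17Chr4g0007051 rose from 8.69 ± 0.939 to 62.9 ± 6.33 TPM, with a log2 fold change of 2.72, a standard error of 0.13 and an adjusted p of 0.000863. MtrunA17Chr5g0419971 and MtrunA17Chr4g0007031 rose by 2.59 and 2.51. The others were a peroxidase (MtrunA17Chr2g0292091) at 3.23 with a standard error of 0.66, a lysine-tRNA ligase (MtrunA17Chr4g0072181) at 3.06 with a standard error of 0.62 and a cytochrome P450 of family 71 (MtrunA17Chr5g0446101) at 2.60 with a standard error of 0.34. The 6 largest decreases named from the same table included 2 genes described as the ethylene-responsive transcription factor ERF017. Of these, MtrunA17Chr2g0301181 fell from 109.6 ± 44.4 to 5.60 ± 6.34 TPM and MtrunA17Chr2g0301191 fell by 4.12 on the log2 scale. The U-box genes MtrunA17Chr4g0059201 and MtrunA17Chr5g0413681, whose domain is found in ubiquitin ligases, had log2 fold changes of -4.00 and -3.81 and standard errors of 0.44 and 0.28. A gene described as the nuclease HARBI1 (MtrunA17Chr4g0070891) fell from 547.3 ± 188.6 to 44.5 ± 44.6 TPM and a CCCH zinc finger gene (MtrunA17Chr3g0113651) from 327.3 ± 55.4 to 31.2 ± 29.5 TPM. For these 6 genes the log2 fold changes in the authors' deposited table ran from -3.72 to -2.10, nearer to 0 than the -4.45 to -3.74 of the fit here. The peroxidase did not pass without wild type replicate 3 (adjusted p = 0.0713), spx1spx3 replicate 2 (0.0855) or spx1spx3 replicate 3 (0.0794), and the ligase without spx1spx3 replicate 2 (0.0852) or 3 (0.0794). Without spx1spx3 replicate 2, both ERF017 genes, the HARBI1 gene and the CCCH gene had an adjusted p of 0.0605 to 0.061.

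Over all genes, 4661 of 27397 were called changed, of which 3536 were higher and 1125 lower in spx1spx3, so that 75.9% of the calls were higher. The wild type and spx1spx3 libraries did not overlap for 42.0% of the genes, where chance gives 10%. With a log2 fold change of at least 1 as well, 1013 were higher and 770 lower. The balance of directions depended on the scaling. The median gene was higher by 0.17 (log2) in spx1spx3 on the TPM scale, and under median-of-ratios scaling, chosen after seeing the data, 1388 genes were higher and 1418 lower, 49.5% higher. Of these, 2475 were also called on the TPM scale, all with the same sign. Relative to that scaling the medians of the lists were -1.18 for flavonoids, 1.63 for nitrogen, -1.59 for iron, -1.21 for defence and 1.29 for peroxidases. All 41 named genes besides SPX1 kept their direction there, which the authors' selection of large changes on these libraries made likely from the outset. The number of calls was 1971 without wild type replicate 1, 1563 without wild type replicate 3, 2502 without spx1spx3 replicate 1, 717 without spx1spx3 replicate 2 and 1179 without spx1spx3 replicate 3. Between 2 and 23 of the named genes lost their call when 1 library was left out, most of them without spx1spx3 replicate 2.

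**Figure D3:**
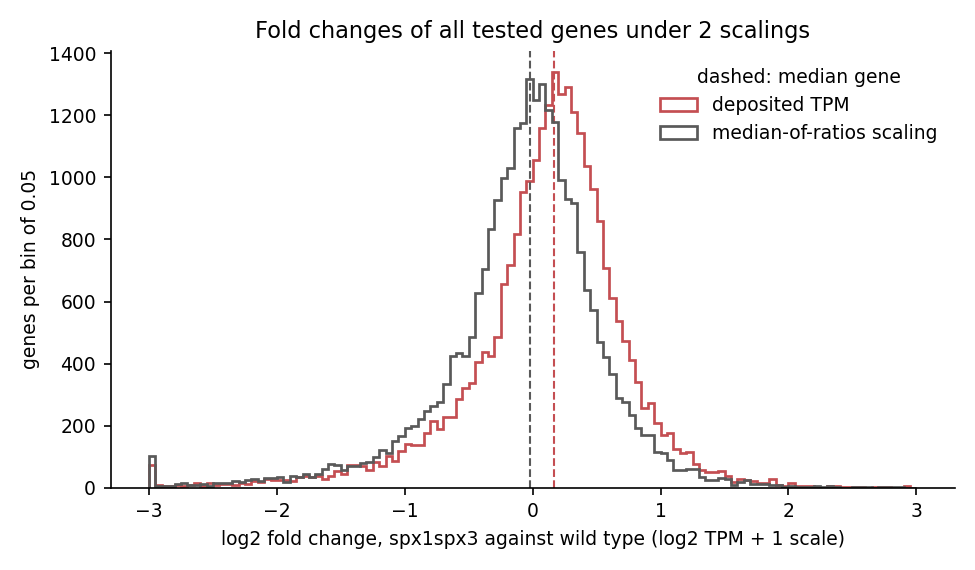
Number of genes per bin of log2 fold change in spx1spx3 against wild type for the 27397 tested genes, from the deposited TPM and after median-of-ratios scaling, with values beyond the axis in the end bins. The median gene, dashed, lies at 0.17 on the TPM scale and at -0.02 after scaling, and under both the end bin on the left holds more genes than that on the right.

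The authors' deposited table names 1020 changed genes, 205 higher and 815 lower in spx1spx3, so that 79.9% are lower. Every gene in it has a mean of at least 5 TPM in both groups and a deposited log2 fold change of 1 or more in size. All 1020 had the same sign in the fit here, and 746 were called, 200 higher and 546 lower, with 0 called in the opposite direction. Under median-of-ratios scaling 699 were called with the same sign. Both the table and the fit rest on the same 6 libraries, so the overlap is not independent evidence. Among the 17798 genes with a mean of at least 5 TPM in both groups, 656 had a log2 ratio of mean TPM of 1 or more and 800 of -1 or less. Measured from the median gene of that set, at 0.165, 358 lay 1 or more above and 1042 lay 1 or more below. The overlap fell to 464 without wild type replicate 1, 485 without wild type replicate 3, 258 without spx1spx3 replicate 2 and 465 without spx1spx3 replicate 3.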

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

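RPKM, median-of-ratios scaling and the floor of 5 TPM were chosen after seeing the data. The count of 4661 changed genes became 1783 (1013 higher) with a log2 fold threshold of 1 and 2806 (1388 higher) with median-of-ratios scaling. It was 3507 with no filter, 4457 with a pseudocount of 0.1, 3694 with RPKM and 3152 of 17798 genes with the floor of 5 TPM. Leaving out 1 library gave 717 to 4487 changed genes, 442 to 3258 higher, 275 to 1229 lower and 258 to 772 of the authors' genes. Fewer libraries leave fewer residual degrees of freedom, and the cause beyond that was not tested. SPX1 ran from -1.58 to -0.64 over these fits, with an adjusted p under 0.05 only without wild type replicate 2 (0.0385). The flavonoid list kept a camera adjusted p above 0.05 and a median below 0 in each fit that tested lists, which leaves out the fold threshold and the floor of 5 TPM. The camera adjusted p of the phosphate list was 0.868 to 0.959 with a library left out, and its direction turned downward without wild type replicate 2 (0.942). With an estimated correlation the nitrogen (0.352) and peroxidase (0.114) lists lost their call. With the replicate number as a block, 1 gene was called, 0 higher and 1 lower, and 0 of the authors' genes, while 7894 genes had an unadjusted p under 0.05 (limma). The numbers share only a label: deviations of same-numbered libraries correlated at -0.31, -0.24 and -0.05, and no wild type library correlated best with its own number. All 41 named genes other than SPX1 kept their direction in all 11 refits. They come from genes that the authors selected for large changes on these libraries, so a kept direction is no independent support. Size-factor scaling and Wald tests of counts, and enrichment of annotated terms, were planned but not run, as the units are not counts and no terms were used here. The simulated recovery of 43% at a fold of 2 does not measure what small changes the real fit can show, as only 200 genes were changed in the simulation. Absolute depth is unknown.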

Other observations

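Other groups of described genes in the authors' table were examined after their descriptions were seen, and their members were chosen by the authors on these samples. Genes for calcium-binding proteins and for transcription factors of the AP2/ERF, WRKY, GRAS and MYB families were mostly lower in spx1spx3. NAC genes, which moved both ways, are given with the groups further below. Of 27 AP2/ERF genes, 20 fell and 2 rose, and all 5 WRKY genes, all 9 GRAS genes and 8 of 9 MYB genes fell. WRKY transcription factor 40 (MtrunA17Chr2g0333851) fell from 164.2 ± 54.1 to 16.3 ± 12.8 TPM (SD, n = 3), the scarecrow 13 gene MtrunA17Chr4g0076091 from 517.3 ± 136.0 to 75.1 ± 38.7 TPM, and the Myb4 gene MtrunA17Chr4g0022901 from 121.1 ± 39.3 to 8.60 ± 4.05 TPM. Of 21 genes for calcium-binding and calmodulin-like proteins 18 fell, with a median log2 fold change of -1.43, and of 29 ubiquitin ligases 25 fell and 1 rose. None of these groups stood apart from the other genes of a table that is mostly lower (camera adjusted p from 0.142 to 0.197). Many genes of these families respond within minutes to touch, wounding or chitin in other plants, and how the roots were harvested is not given in the sources used here. No test here separates genotype from handling. Without spx1spx3 replicate 2 the counts that fell were 3 for AP2/ERF, 3 for WRKY, 2 for MYB, 1 for calcium-binding and 10 for ubiquitin ligase genes, and WRKY transcription factor 40 had an adjusted p of 0.0534. Without wild type replicate 1 they were 8 for AP2/ERF, 3 for MYB and 7 for calcium-binding genes. Of MYB genes 5 fell without wild type replicate 3 or spx1spx3 replicate 1 or 3, and of calcium-binding genes 9 without wild type replicate 3 and 10 without spx1spx3 replicate 1.

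Of 17 genes for abscisic acid and dehydration proteins, 9 fell and 2 rose. The 2 that rose were both described as abscisic acid receptors PYL4-like, MtrunA17Chr4g0005501 from 65.6 ± 20.97 to 167.0 ± 28.0 TPM and MtrunA17Chr5g0437611 from 36.9 ± 13.8 to 110.1 ± 28.7 TPM, while the phosphatase 2C gene MtrunA17Chr5g0430481, of the family that these receptors inhibit, fell from 105.9 ± 26.9 to 18.0 ± 5.88 TPM. Of 31 cell wall genes, 15 fell and 6 rose, with expansin A10 (MtrunA17Chr4g0042521) at 75.9 ± 13.4 TPM in wild type and 221.8 ± 29.9 TPM in spx1spx3. Receptor-like kinases moved both ways, with 10 higher and 16 lower of 28. Of 5 genes of the jasmonate pathway 3 fell, of 15 UDP-glucosyltransferases 7 fell and 2 rose, of 14 auxin-related genes 6 fell and 1 rose, of 10 NAC genes 3 fell and 2 rose, and of 6 HMG-CoA reductase and terpenoid genes 3 fell. Of 6 cell division and chromatin genes 2 rose and 1 fell, and with 1 library left out 1 or 2 rose and 0 to 2 fell. With 1 library left out, the counts that fell were 2 to 13 for abscisic acid, 3 to 15 for cell wall, 7 to 14 for receptor-like kinase, 2 to 6 for UDP-glucosyltransferase and 0 to 2 for jasmonate genes. They were 0 to 8 for auxin and for NAC genes and 0 to 4 for HMG-CoA reductase and terpenoid genes. The fits without spx1spx3 replicate 2 gave the lowest of these except for NAC genes, with 1 against 0 without wild type replicate 3 or spx1spx3 replicate 3. Of cell wall genes 3 rose without any library other than wild type replicate 1, and of receptor-like kinases 6 rose without spx1spx3 replicate 2. In that last fit no NAC gene rose, and no auxin gene rose when any spx1spx3 library was left out. With no filter on low values, 9 cell wall, 4 UDP-glucosyltransferase and 1 jasmonate gene fell, and under median-of-ratios scaling 3 cell wall genes and no auxin gene rose. The PYL4-like genes did not pass without wild type replicate 1 (adjusted p of 0.0576 and 0.0642), spx1spx3 replicate 1 (0.0514 and 0.0539) or spx1spx3 replicate 2 (0.0754 and 0.0804), nor MtrunA17Chr5g0437611 without wild type replicate 3 (0.0543).

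Of the tests below, those of depth, of the splits of the libraries, of the median gene for the flavonoid list and of shared chalcone synthase reads were chosen only after the result was seen. The 4661 calls came from the real grouping, and the highest count among the other splits of the 6 libraries into 3 and 3 was 0. The real grouping was 1 of 10 splits with as many calls, and 10 splits are too few for a share under 0.05.

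Whether the larger number of higher than lower genes comes from the per-million scale cannot be told apart from a moderate rise of many genes. Median-of-ratios scaling took the share of calls that are higher from 75.9% to 49.5%, but it centres the median gene, which by itself brings the balance near even. With RPKM, which does not centre the median gene, the share was 67.5% and the median log2 fold change 0.078, so the balance moved with the scale there too. A few abundant genes taking more of the wild type libraries are argued against, since leaving out the 100 most abundant genes left the median log2 fold change of the others at 0.176, against 0.170 before. Whether lower depth of the spx1spx3 libraries plays a part stays open. TPM is scaled to each library's total, so fewer reads add noise to rare genes but do not by themselves raise their mean. The median log2 ratio was higher by 0.0946 at 5 to 10 TPM (0.290, 95% interval 0.275 to 0.304 across genes) than at 1 to 2 TPM (0.195, 0.153 to 0.238). For this reason that difference decides nothing about depth. Above 10 TPM the ratio fell to 0.155 at 20 to 50 TPM, 0.038 at 50 to 100 and -0.045 at 100 to 1000, so the shift lay in the less abundant genes.

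The authors' table, with its log2 fold change of 1 or more in size, holds 205 higher and 815 lower genes, while the calls on the TPM scale without a fold threshold were 3536 higher and 1125 lower. The thresholds make part of this contrast, since the calls with a log2 fold change of at least 1 were 1013 and 770, and at the table's floor of 5 TPM the log2 ratio of mean TPM alone was 1 or more for 656 genes and -1 or less for 800. A candidate explanation for the rest is that the deposited log2 fold changes were centred on the median gene. Of the table's genes, 99.5% lie 1 or more (log2) from the median gene, against 86.3% from 0, the smallest log2 ratio of mean TPM among its higher genes is 1.25 and the one nearest 0 among its lower genes is -0.83. Centring alone does not give the deposited values, as 966 of the 1020 lie nearer to 0 than the log2 ratio less the median gene (MtrunA17Chr2g0301181 at -2.10, against a log2 ratio of -4.29), and no biological explanation was tested for this pattern.

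The lower flavonoid and isoflavonoid genes are the pattern closest to the study's question. A scale factor that moves all genes alike is argued against, since the median of all tested genes was at 0.169, above 0. Whether a single library is the cause stays open. The median of the 14 members stayed between -1.33 and -0.884 with any library left out. The authors had selected these members as lower on the same libraries, which made a kept median likely from the outset, so it decides nothing. All lower genes of the table, selected by the authors on these libraries, kept a median of -1.23 or lower as well, so this does not set the flavonoid genes apart. The count that passed the test fell from 6 to 1 without wild type replicate 3, spx1spx3 replicate 2 or spx1spx3 replicate 3. Fewer libraries leave fewer residual degrees of freedom, so these lost calls do not by themselves show that a single library drove them. Shared reads of chalcone synthase copies stay open: the 5 other members had a median of -0.846, but the authors selected them as lower, and no lower gene of the table had a log2 fold change in the fit here nearer 0 than -0.72, so this value decides nothing. A genotype effect stays open as a hypothesis, as do differences in tissue, handling or growth. The shoot marker MtrunA17Chr4g0051941 varied between wild type libraries in the same order as the isoflavone synthase MtrunA17Chr4g0046331, which did not pass the test. The dehydratase and the chalcone synthase family genes that fell had other orders, with wild type replicate 1 highest. Wild type replicate 2 was still the lowest wild type library for MtrunA17Chr1g0201371, MtrunA17Chr1g0201381 and MtrunA17Chr1g0201421, as for the shoot marker. Wild type replicate 3 was the lowest for MtrunA17Chr1g0201391 and the dehydratase. These orders decide nothing about tissue.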
